A study of Rattus norvegicus with 18 samples.

How the data were processed

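RNA was measured by sequencing in 18 libraries of beta cells from rat pancreatic islets. Per the labels' protocols, islets from old and young rats were cultured overnight in RPMI1640 medium with 10% fetal bovine serum and 11.1 mM glucose and exposed to 10 micromolar EdU. EdU is a thymidine analogue that cells build into newly made DNA, so it marks cells that passed through S phase during the exposure. Sorted cells were lysed in the buffer of a kit made for fixed tissue, with proteinase K, and libraries were made with a stranded total RNA kit, per the labels' protocols. The series text describes 9 islet batches of 2 rats each, with a replicating and a quiescent beta cell sample per batch. The labels give age, replicative status and a replicate number, and these placed the libraries in 4 groups: 4 old quiescent, 4 old replicative, 5 young quiescent and 5 young replicative. The ages in weeks or months, the gate used in the sort and the number of cells per library are not given in the sources used here.

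The deposited count table holds whole-number read counts per Ensembl rat gene ID for 27654 genes, with no normalization by the authors. STAR, DESeq2 and the rat genome build rn6 are named in the submitters' processing notes with no role or version. The counting program, the annotation release and the strand setting are not given in the sources used here, so genes that overlap on opposite strands, and genes with near-identical copies, carry an uncertainty in their counts that was not measured. The second deposited table holds log2 values. Recomputing it from the counts showed that each log2 value is the log2 of the count divided by a median-of-ratios size factor, plus 1, with a largest difference of 5.2e-14. No per-sample column was left unused.

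The files do not pair gene IDs with gene names. The reference table at hand has 47357 genes, of which 0 carry an Ensembl ID, so 0 of the 27654 IDs could be matched to a symbol. For this reason the 35 gene lists fixed before the data were examined (cell cycle, beta cell maturity, other islet and pancreatic cell types, signalling and metabolic pathways) were not run, and no check by marker genes of purity, of sex or of mitochondrial RNA was made. The rule for named genes, also fixed before the data were examined, took the genes with the smallest quasi-likelihood p in each direction among those past the threshold with an absolute log2 fold change of at least 1 and an average log2 CPM of at least 2. Its condition that a gene have a proper symbol, and its list of genes to be named in any case, could not be applied. At most 2 IDs per direction and comparison are printed, a limit set before their values were seen.

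Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults by group (a minimum count of 10, here 1.39 CPM in at least 4 libraries, and a total of at least 15), which left 14920 genes and removed 12734. Library sizes were scaled by TMM. The main design was a single model with 4 group means over all 18 libraries, with robust dispersion estimates and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F value. The comparisons were replicative against quiescent within each age, old against young within each status, and the interaction of age and status. CPM values used the TMM-scaled library sizes. Because the labels name each library as a separate replicate and the series text names separate batches of 2 rats, the unit behind the p-values is a library from a batch of pooled rats. The main model sets differences against a spread averaged over all 4 groups, not that of the groups compared. It also counts the quiescent and replicating libraries of a batch as independent. Old and young libraries came from different batches, and no sequencing batch or date is given in the labels.

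The model with 4 groups shares a single spread estimate per gene. The spread within groups differed (values stand in the results), so each comparison was also fitted on its own 2 groups, an alternative fixed before the data were examined, and both counts are given together. In that fit the filter was recomputed on the libraries compared. Other alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), no low-count filter, a filter at 1 CPM in every library of a group, thinning of all libraries to 2723660 counts, removal of the 10 most abundant genes, limma-trend on the deposited log2 values, the replicate number as a block (fixed, or random with statmod 1.5.0), and leaving out each library in turn. Chosen after seeing the data were limma-voom with 1 quality weight per group, the block within the 2-group fits, and set tests of the genes called in a comparison within the comparison that shares no library with it.

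Library measures were compared by exact permutation tests of the difference in means, two-sided, adjusted over a family of 20. These exchanged libraries freely between groups and did not use the batches. Where a group had 0 counts of a gene, its fold was bounded with 3 counts over the group's libraries, and such floors cover counting error only. Libraries of a group were compared by a chi-square of their counts over genes. The smallest chi-square per degree of freedom was 4.18, above the sampling noise of a library counted again, so no library was treated as a duplicate.

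The main test was checked on simulated counts for the 14920 genes with the real library sizes and the fitted dispersions, in which 200 genes were changed. For replication in old cells it recovered 2% of genes changed 2-fold and 29% of those changed 4-fold, and for replication in young cells 2% and 42%. For age among quiescent cells it recovered 1% and 45%, for age among replicative cells 3% and 38%, and for the interaction 1% and 25%. Unchanged genes were called 2, 4, 2, 2 and 1 times, in that order. A second simulation of the 14920 genes had no changed gene and gave each group its own spread. There the 4-group model called 192 genes for replication in old cells, 0 in young cells, 0 for age among quiescent cells, 458 for age among replicative cells and 20 for the interaction, while the 2-group fits called 0 in each of the 4 comparisons they can make.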

Results

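The series asked how replicating beta cells differ from quiescent ones in islets of old and of young rats. Total counts per library ran from 2723660 (young quiescent replicate 2) to 14222719 (young quiescent replicate 4). Old quiescent libraries held 4639863 to 10365264 counts, old replicative libraries 2975086 to 8639541, and young replicative libraries 5439091 to 8242896. Total counts did not differ past the threshold in any of the 4 comparisons of groups (exact permutation tests, two-sided, p = 0.286 to 0.730; smallest adjusted p = 0.381). Genes are given by their Ensembl rat IDs because the files do not pair them with names.

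The old replicative libraries were the most unlike each other. Their mean Spearman correlation with the other libraries of the group was 0.725 ± 0.0398 (SD, n = 4), against 0.969 ± 0.00315 (SD, n = 4) in old quiescent, 0.960 ± 0.00961 (SD, n = 5) in young quiescent and 0.892 ± 0.0332 (SD, n = 5) in young replicative libraries. The biological coefficient of variation within groups, the relative spread beyond counting noise, was 0.293 in old quiescent, 1.29 in old replicative, 0.347 in young quiescent and 0.701 in young replicative libraries. Old replicative replicate 3, the shallowest of its group at 2975086 counts, lay alone at 292 on the first principal component, which held 28.0% of the variance. Thinned to 2723660 counts, old replicative libraries held 13738 ± 2286 detected genes (SD, n = 4) and old quiescent libraries 15971 ± 785 (SD, n = 4). This difference did not pass the threshold (exact permutation test, two-sided, p = 0.143, adjusted p = 0.286). Nor did that between old replicative libraries and young replicative ones at 17795 ± 3392 genes (SD, n = 5; exact p = 0.0873, adjusted p = 0.218). With so few libraries, neither result shows that the groups were equal. By replicate number, old quiescent and old replicative libraries held 16847 and 16888, 15975 and 13899, 16121 and 11730, and 14942 and 12435 genes, a pairing the test did not use.

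**Figure D1:**
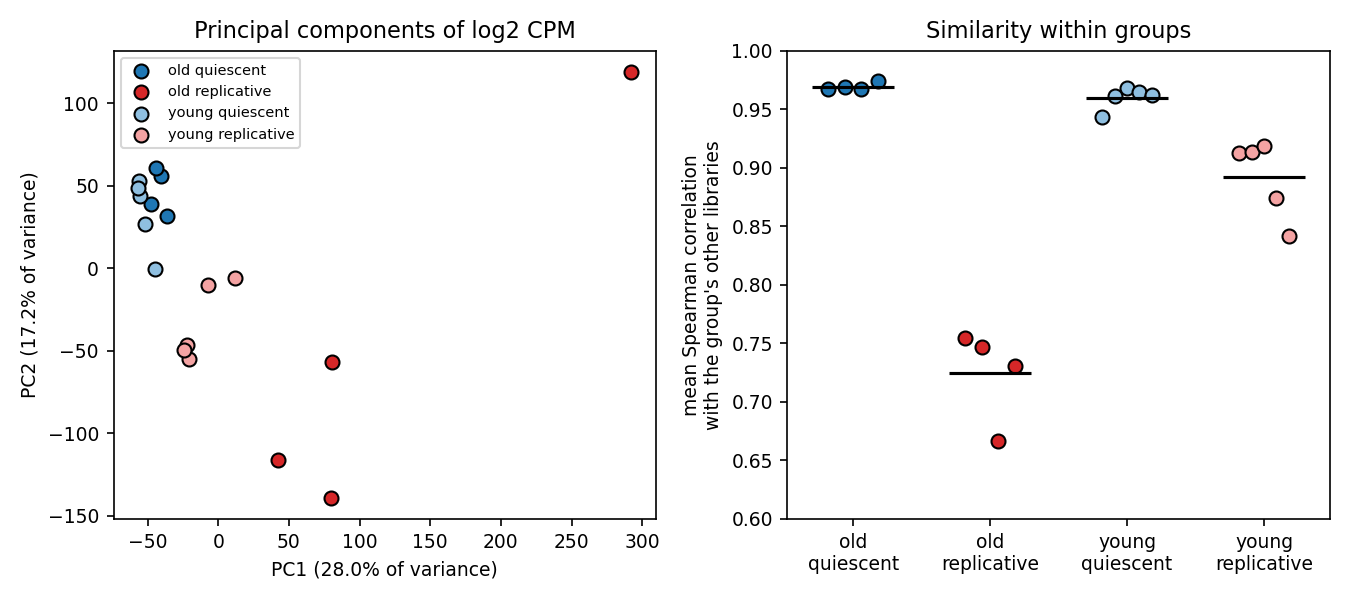
The left panel plots each of the 18 libraries by its first (28.0% of variance) and second (17.2%) principal component of log2 CPM, and the right panel each library's mean Spearman correlation with the other libraries of its group, on an axis that starts at 0.6, with bars at the group means. Old replicative libraries spread widest in both, with a group mean correlation of 0.725 against 0.969 in old quiescent libraries.

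The most abundant transcripts took a smaller share of the RNA in replicative than in quiescent libraries. The 10 genes with the highest counts over all libraries held 25.9% ± 1.69 of counts in old quiescent (SD, n = 4) and 16.3% ± 4.45 in old replicative libraries (SD, n = 4), with no overlap of the groups. In young islets they held 27.6% ± 1.92 in quiescent (SD, n = 5) and 20.8% ± 1.05 in replicative libraries (SD, n = 5), again with no overlap. Both exact permutation p-values, 0.0286 in old and 0.00794 in young, are the smallest this test can give. Neither passed adjustment over the 20 tests of library measures (adjusted p = 0.114 for both). The test exchanged libraries freely, although each batch gave a quiescent and a replicating sample. Exchange within batches would allow fewer arrangements, so its smallest possible p would be larger. The gene with the highest counts in the series held 6.21% ± 0.296 of counts in old quiescent and 3.54% ± 1.07 in old replicative libraries (SD, n = 4 each). Its log2 fold change was -1.09 (SE 0.270) in old cells, where it passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0102), and -0.69 (SE 0.240) in young cells, where it did not (edgeR adjusted p = 0.206). The second most abundant gene changed by -1.23 (SE 0.318) in old cells (edgeR adjusted p = 0.0131) and had a value of -0.66 (SE 0.281) in young cells (edgeR adjusted p = 0.447).

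In replicating cells of old islets, ENSRNOG00000028137 rose from 2.00 ± 0.922 CPM in old quiescent to 1320 ± 488 CPM in old replicative libraries (SD, n = 4 each), a log2 fold change of 9.36 (SE 0.466). ENSRNOG00000009339 rose from 0.925 ± 0.324 to 497 ± 152 CPM (SD, n = 4 each), a log2 fold change of 9.12 (SE 0.443). Both had an edgeR adjusted p of 4.30e-12. Among genes that fell, ENSRNOG00000023007 went from 374 ± 56.0 to 87.0 ± 21.01 CPM (SD, n = 4 each; log2 fold change -2.10, SE 0.284, edgeR adjusted p = 2.49e-05). ENSRNOG00000024848 went from 79.2 ± 35.4 to 0.131 ± 0.261 CPM (log2 fold change -8.74, SE 1.11, edgeR adjusted p = 9.68e-06). It had counts in 1 of the 4 old replicative libraries, 5 in replicate 2, so the size of its fold is loosely set, and it was -10.61 with thinned counts. The gene lost the call in limma-voom with quality weights, per sample (log2 fold change -9.08, adjusted p = 0.124) or per group (-8.88, adjusted p = 0.147), with a fold as large. Its adjusted p ranged from 7.13e-16 to 0.147 among all alternatives.

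Of 14920 genes tested, 2053 differed between replicative and quiescent cells of old islets, 1068 higher and 985 lower in replicative cells. Which direction held more genes depended on the scaling, with 937 higher and 1246 lower under upper-quartile factors and 1209 and 799 under RLE factors. The higher genes took 1.53% ± 0.252 of counts in old quiescent and 9.93% ± 2.64 in old replicative libraries, and the lower genes 38.9% ± 1.36 and 20.95% ± 4.66 (SD, n = 4 each). Both lists were chosen for this difference in these libraries, so the shares give its size and do not test it. The median log2 fold change was 3.61 among higher genes and -1.88 among lower genes. It was the same when the 16 higher and 188 lower genes with a group at 0 counts were set at their bounds. Among the 515 genes with an average log2 CPM of 8 or more, 14 were higher and 165 lower. Among the 4716 genes between 4 and 6, 445 were higher and 151 lower, and among the 3761 between 2 and 4, 335 and 119. Among the 3363 genes under 2 the balance turned again, with 105 higher and 283 lower. Groups did not overlap for 2464 genes, 16.5% of those tested, where chance gives 2.86% if both groups have the same spread. Their coefficients of variation, 0.293 in old quiescent and 1.29 in old replicative libraries, differ, which raises the chance share. By how much was not computed, so the excess cannot be read as changed genes alone. Fitted on the 8 old libraries alone, the comparison called 540 genes, 395 higher and 145 lower, of which 533 were also called in the model of all 4 groups. Simulated libraries with the groups' unequal spreads and no changed gene gave 192 calls in the 4-group model and 0 in the 2-group fit. Leaving out old quiescent replicate 1, 3 or 4 lowered the 4-group count to 1351, 1153 or 1134.

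In young islets the same pair of genes had the smallest p among higher genes that met the naming rule. ENSRNOG00000028137 rose from 10.5 ± 4.53 to 1566 ± 354 CPM (SD, n = 5 each; log2 fold change 7.25, SE 0.375) and ENSRNOG00000009339 from 3.65 ± 1.59 to 517 ± 136 CPM (SD, n = 5 each; log2 fold change 7.19, SE 0.355). Both had an edgeR adjusted p of 6.86e-12. The genes that fell did so by less. ENSRNOG00000011016 went from 326 ± 66.1 to 147 ± 22.5 CPM (SD, n = 5 each; log2 fold change -1.15, SE 0.200, edgeR adjusted p = 0.000646). ENSRNOG00000047374 went from 1204 ± 324 to 584 ± 74.2 CPM (SD, n = 5 each; log2 fold change -1.04, SE 0.206, edgeR adjusted p = 0.00284). In old cells these 2 genes fell by 1.15 and 1.33 on the log2 scale (edgeR adjusted p = 0.00159 and 0.000596), and ENSRNOG00000023007, named above, fell by 1.00 in young cells (edgeR adjusted p = 0.0233).

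In young islets 368 of the 14920 genes differed, 336 higher and 32 lower in replicative cells. The higher genes had a median log2 fold change of 3.74 and took 0.589% ± 0.0378 of counts in quiescent and 4.13% ± 0.781 in replicative libraries (SD, n = 5 each). The lower genes had a median of -1.03 and went from 1.52% ± 0.221 to 0.851% ± 0.0418 of counts (SD, n = 5 each). These shares too come from the libraries that chose the lists and do not test the difference. Groups did not overlap for 1058 genes, 7.09% of those tested, where chance gives 0.794% if both groups have the same spread. The unequal spreads of the young groups (0.347 and 0.701) raise that share by an amount not computed. Fitted on the 10 young libraries alone, the comparison called 786 genes, 624 higher and 162 lower, of which 359 were also called in the model of all 4 groups. In limma-voom with quality weights 2952 genes were called, 1695 higher and 1257 lower.

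Genes higher in replicating young cells were also higher in replicating old cells, in comparisons that share no library. In the 4-group model both lists rest on the same filter and the same spread estimate per gene, while the 2-group fits share neither. Of the 336 genes higher in young islets, 309 were called higher in old islets, where independent lists would share 24.1, and the median log2 fold change of the 336 was 3.74 in young and 3.89 in old cells. These 336 genes took 0.546% ± 0.0310 of counts in old quiescent and 3.60% ± 0.775 in old replicative libraries (SD, n = 4 each). Of the 32 lower genes, 26 were called lower in old islets (2.11 for independent lists, Fisher's exact test, one-sided, p = 9.26e-26), with medians of -1.03 in young and -1.20 in old cells. That test treats genes as independent units, which they are not, so its p is no measure of the spread between rats. No gene was called in opposite directions in edgeR's 4-group model or in its 2-group fits, and all 336 higher and all 32 lower genes had the same sign in old cells. In the 2-group fits, 218 genes were called higher at both ages (370 in old and 563 in young among 11914 genes in both fits; 17.5 for independent lists) and 23 lower (139 and 162; 1.89).

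As sets, the young lists moved the same way in old cells (camera with a preset correlation, adjusted p = 1.02e-132 for higher and 1.26e-13 for lower genes; with an estimated correlation, adjusted p = 3.71e-05 and 0.00116). The 1068 genes higher in old replicative cells were also shifted upward in young cells, with 997 of them above 0 and a median log2 fold change of 1.26 against 3.61 in old cells. The 985 lower genes had 772 below 0 and a median of -0.39 in young cells, against -1.88 in old cells. Both shifts were past the threshold with an estimated correlation (adjusted p = 3.71e-05 and 0.000287), as they were with fry (adjusted p = 1.69e-06 and 9.94e-06). Medians in the comparison that chose a list are pushed outward by that choice, so these pairs of medians do not test a difference between ages. Across all 14920 genes the fold changes of the 2 ages correlated with a Pearson r of 0.544 and a Spearman rho of 0.462, and with a Pearson r of 0.869 across the 3080 genes with an average log2 CPM of 6 or more. Genes are not independent replicates, so these values describe the pattern and carry no p-value.

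**Figure D2:**
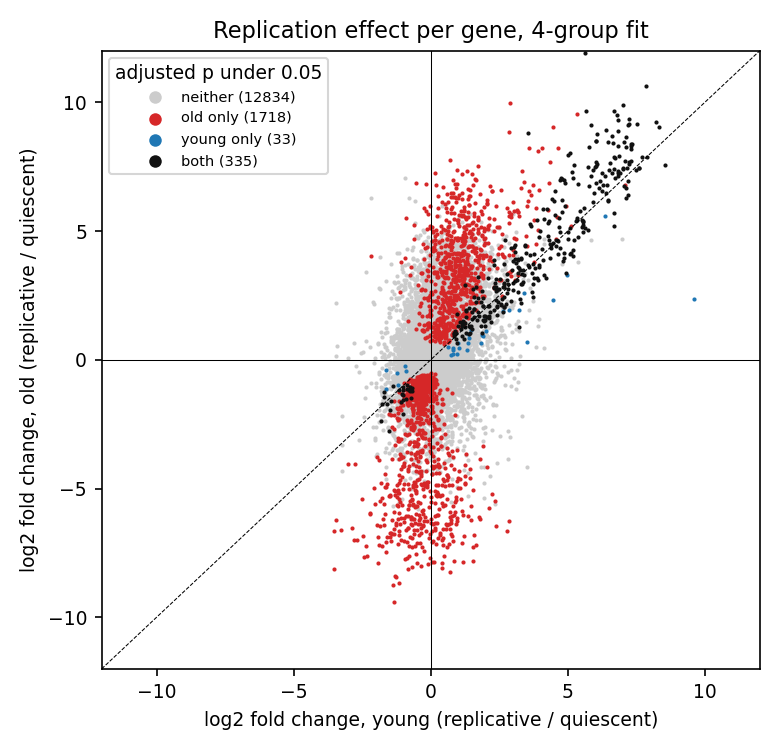
Each point is a gene of the 14920 tested, placed by its log2 fold change between replicative and quiescent cells in young (horizontal) and old islets (vertical) from the 4-group model, with colours for an adjusted p under 0.05 at neither age (12834), in old alone (1718), in young alone (33) or at both ages (335), and a dashed line of equal change. The genes past the threshold at both ages lie along the line, and most of those past it in old islets alone spread vertically; a call at a single age is no test of a difference between ages.

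Whether the replication effect differed with age was tested by the interaction. It passed the threshold for 4 of 14920 genes, and all 4 values were negative, a lower replication effect in old than in young cells. Simulated libraries with the groups' unequal spreads and no changed gene gave 20 calls in this model, more than the 4 observed. The direction of the calls changed with the tool and the model. In limma-voom with quality weights 2 genes were called, both with a positive value and neither among the 4. With the replicate number as a fixed block 11 were called, 9 positive and 2 negative, of which 1 was among the 4. ENSRNOG00000024848 had an interaction of -7.37 on the log2 scale (SE 1.23, edgeR adjusted p = 0.0291), with 10.2 ± 4.94 CPM in young quiescent and 3.93 ± 4.25 CPM in young replicative libraries (SD, n = 5 each) beside the old values above. With thinned counts its interaction was -9.25 and the call was lost (edgeR adjusted p = 0.0574). ENSRNOG00000062279 had 0 counts in all 4 old replicative libraries, at least 37.0-fold lower than old quiescent and at least 68.7-fold lower than young replicative libraries by a floor of 3 counts over the group (edgeR adjusted p = 0.0291). The other two genes also had 0 counts in all 4 old replicative libraries (edgeR adjusted p = 0.0291 and 0.0420). For the genes named above, the interaction was not past the threshold: 2.12 for ENSRNOG00000028137 (edgeR adjusted p = 0.0754), 1.93 for ENSRNOG00000009339 (edgeR adjusted p = 0.111) and -1.10 for ENSRNOG00000023007 (edgeR adjusted p = 0.252). The interaction count was 0 in limma-voom with 1 weight per group and 296 in DESeq2, and it ran from 0 to 231 when single libraries were left out, with the highest value without old replicative replicate 1. ENSRNOG00000024848 and ENSRNOG00000062279 lost the call in 14 and 17 of 30 alternatives.

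Among quiescent cells, 4 genes differed between old and young islets, 3 higher and 1 lower in old. ENSRNOG00000007092 stood at 2582 ± 987 CPM in old (SD, n = 4) and 469 ± 190 CPM in young libraries (SD, n = 5), a log2 difference of 2.46 (SE 0.369, edgeR adjusted p = 0.0118). ENSRNOG00000006957 stood at 25.2 ± 19.4 CPM in old (SD, n = 4) and 1.32 ± 1.09 CPM in young libraries (SD, n = 5), a log2 difference of 4.28 (SE 0.695, edgeR adjusted p = 0.0149). The third higher gene rose by 2.85 (SE 0.485, edgeR adjusted p = 0.0245). ENSRNOG00000028137, which rose with replication at both ages, was lower in old quiescent cells, at 2.00 against 10.5 CPM, a log2 difference of -2.36 (SE 0.368, edgeR adjusted p = 0.0118). At an unadjusted p under 0.05, 733 genes differed. With no changed gene, evenly spread p-values would give 746, and simulated libraries with the groups' unequal spreads gave 10 in the same model. Fitted on the 9 quiescent libraries alone, the comparison called 258 genes, 135 higher and 123 lower in old, and these included all 4. Groups did not overlap for 908 genes, 6.09% of those tested, where chance gives 1.59% if both groups have the same spread (0.293 in old and 0.347 in young quiescent libraries). The 4-group count fell to 0 without young quiescent replicate 2 or 3 and rose to 13 without old quiescent replicate 1. ENSRNOG00000007092, ENSRNOG00000006957 and ENSRNOG00000028137 lost the call in 3, 6 and 5 of 21 alternatives, and the last did so when all libraries were thinned to equal depth (log2 difference -2.23, edgeR adjusted p = 0.118; range over its alternatives 4.06e-06 to 1.00), with nearly the same fold.

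Among replicative cells, age differences were larger in number in the 4-group model and few in the fit of these libraries alone. ENSRNOG00000054890 stood at 559 ± 147 CPM in old (SD, n = 4) and 86.4 ± 42.1 CPM in young replicative libraries (SD, n = 5), a log2 difference of 2.69 (SE 0.332, edgeR adjusted p = 0.000544). ENSRNOG00000002461 stood at 452 ± 317 and 47.4 ± 15.99 CPM, a log2 difference of 3.25 (SE 0.437, edgeR adjusted p = 0.00117). ENSRNOG00000051989 had 0 counts in all 4 old replicative libraries and was at least 90.6-fold lower than in young replicative ones (edgeR adjusted p = 0.00126). ENSRNOG00000009572 stood at 0.292 ± 0.339 CPM in old (SD, n = 4) and 26.8 ± 12.2 CPM in young libraries (SD, n = 5), a log2 difference of -6.66 (SE 1.01, edgeR adjusted p = 0.00126). Both genes that rose were also past the threshold in the fit of the 9 replicative libraries alone (edgeR adjusted p = 0.00413 and 0.00445; ranges over all alternatives 2.40e-10 to 0.0332 and 1.02e-09 to 0.0350). Both that fell were not (edgeR adjusted p = 0.0722 and 0.0542; ranges 8.20e-10 to 0.181 and 1.15e-11 to 0.560), with nearly the same fold: the log2 difference of ENSRNOG00000009572 was -6.55 there against -6.66, and the fitted value of ENSRNOG00000051989, which depends on the prior count, -9.32 against -9.38.

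The 4-group model called 1069 genes among replicative cells, 491 higher in old with a median log2 difference of 2.73 and 578 lower with a median of -4.53, or -3.63 with the 174 lower genes that had a group at 0 counts set at their bounds. Which direction held more genes depended on the setting. The split was 373 higher and 813 lower with upper-quartile scaling, 508 and 370 with the filter at 1 CPM, and 226 and 5 in limma-voom with quality weights. Fitted on the 9 replicative libraries alone, the comparison called 62 genes, 58 higher and 4 lower, and all 62 were among the 1069. Groups did not overlap for 950 genes, 6.37% of those tested, where chance gives 1.59% if both groups have the same spread. The unequal spreads of the replicative groups (1.29 in old and 0.701 in young) raise that share by an amount not computed. Simulated libraries with these unequal spreads and no changed gene gave 458 calls in the 4-group model and 0 in the 2-group fit.

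The age differences of the replicative cells were partly shared by the quiescent cells of the same batches. In the 2-group fits, 7 genes were higher in old cells of both kinds, against 0.603 for independent lists (129 and 57 genes, Fisher's exact test, one-sided, p = 2.16e-06), and 1 was lower in both. Fisher's test treats genes as independent units, which they are not, so its p is no measure of the spread between rats. Of the 491 genes higher in old replicative cells, 408 were above 0 among quiescent cells (median log2 difference 0.57; camera with an estimated correlation, adjusted p = 0.0124; fry adjusted p = 0.0421). Of the 578 lower genes, 419 were below 0 (median -0.26; camera with an estimated correlation, adjusted p = 0.00335). ENSRNOG00000006957 was past the threshold in both, at 62.7 ± 31.4 CPM in old (SD, n = 4) and 1.93 ± 0.875 CPM in young replicative libraries (SD, n = 5), a log2 difference of 5.01 (edgeR adjusted p = 0.00120). The series text describes a quiescent and a replicating sample from each batch, so these comparisons share no library but share rats, and differences between the batches of rats enter both.

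**Figure D3:**
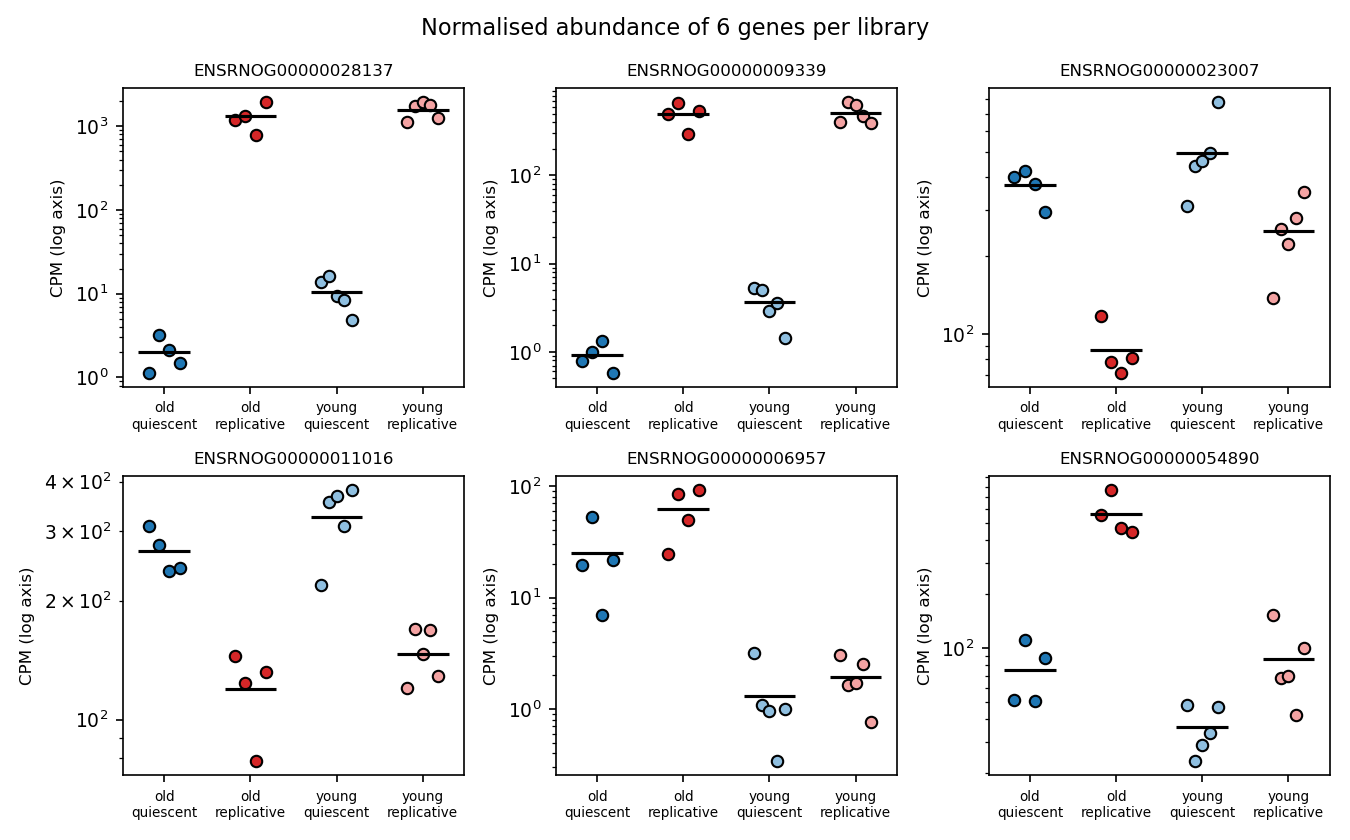
Each panel plots a gene's CPM on a log axis in each of the 18 libraries by group, with bars at the group means. ENSRNOG00000028137 and ENSRNOG00000009339 separate replicative from quiescent libraries at both ages, ENSRNOG00000023007 and ENSRNOG00000011016 have lower means in replicative libraries at both ages, and ENSRNOG00000006957 and ENSRNOG00000054890 have higher means in old libraries, the latter past the threshold among replicative cells (edgeR adjusted p = 0.000544) and not among quiescent ones (edgeR adjusted p = 0.447).

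**Figure D4:**
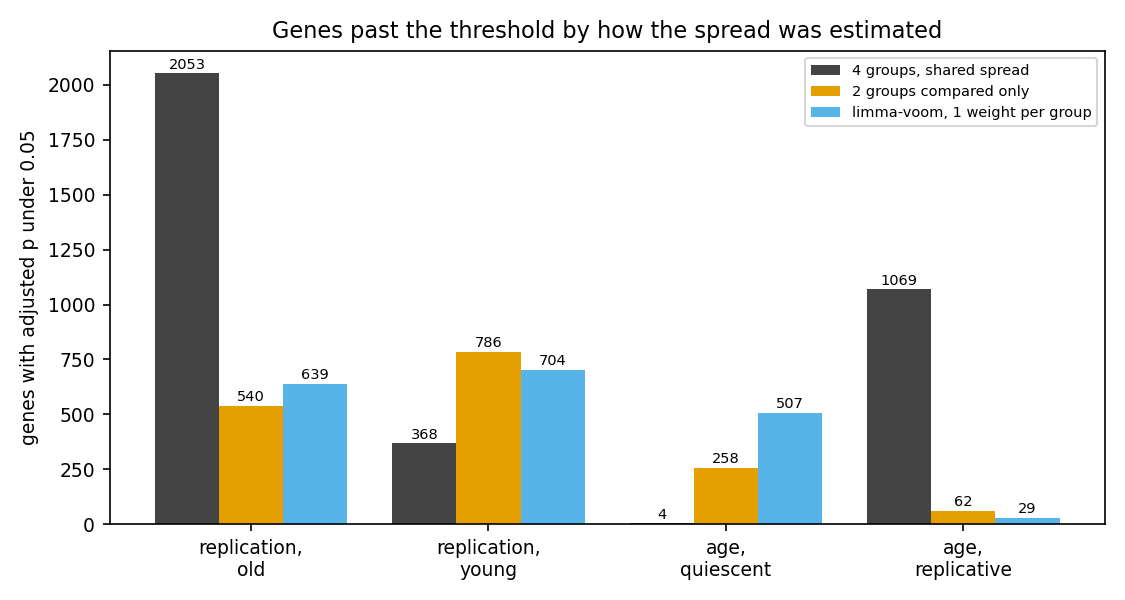
Bars give the number of genes with an adjusted p under 0.05 in each of 4 comparisons, from the model of 4 groups with a shared spread, the fit of the 2 groups compared, and limma-voom with 1 quality weight per group (chosen after seeing the data). The order of old and young reverses between fits: replication gave 2053 genes in old and 368 in young islets in the 4-group model, and 540 and 786 in the 2-group fits.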

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

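The tests of shared zeros in other libraries, of loss among weakly expressed genes and of unequal residual RNA were chosen after the patterns had been seen. The comparison of counts between fits was set before its result was seen. For the 2-group fits the number of splits drawn was raised from 60 to 100 after a first run had been seen. Of 76 groups of values tested for a library far from the rest, 6 gave one, and chance gives about 1 in 20.

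More genes passed the threshold for replication in old than in young islets (2053 against 368). The spread estimate shared by all 4 groups remains open as a cause of that order: with each comparison fitted on its own 2 groups, with the filter recomputed on them, the old count was 0.687 times the young one (540 against 786), although that fit still pools old replicative with old quiescent libraries. Loss of weakly expressed genes from the old replicative libraries is argued against as the whole cause of the 4-group order. Among genes of average log2 CPM 6 or more the old count in that model was still 4.77 times the young one (615 against 129). That ratio cannot tell whether such loss adds to the count, because unequal spreads alone gave 192 calls in old and 0 in young simulated libraries with no changed gene. For age the order also turned between fits: the replicative count (1069) exceeded the quiescent one (4) in the 4-group model, and in the 2-group fits it was 0.24 times as large (62 against 258). A biological difference in how variable replicating cells of old islets are, or in the number of cells sorted, stays open and was not tested.

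Other splits of the same libraries were set against each count. They mix the groups compared, which can widen the spread within groups and lower their counts, so a real split that ranks first does not exclude chance. For replication in old islets all 35 possible splits were run, so 1 of 35 is the smallest share these splits can give. The splits for replication did not use the batches. Exchange within batches would allow fewer splits, so the smallest share would be larger. For replication in old islets, 1 of 35 splits, the real one, gave as many genes (2053, highest other 171, and in the 2-group fit 1 of 35, with 540 and 0). In young islets it was 1 of 60 (368, highest other 14, and in the 2-group fit 1 of 100, with 786 and 18). For age among replicative cells it was 1 of 60 (1069, highest other 604) and, in the 2-group fit, 1 of 100 (62, highest other 5). For age among quiescent cells it was 2 of 60 (4, highest other 4) and, in the 2-group fit, 2 of 100 (258, highest other 565). The split with 565 genes set old quiescent replicates 2, 3 and 4 with young quiescent replicate 4 against the rest and so differed from the real split by an exchange of old quiescent replicate 1 with young quiescent replicate 4; what sets these libraries apart was not tested. For the interaction the splits moved same-numbered libraries of an age together, although no source used here states that the numbers pair them. Of these, 2 of 60 gave as many (4, highest other 18), and the split with 18 exchanged the libraries of old replicate 1 with those of young replicate 5. Simulated libraries with unequal group spreads and no changed gene gave 20 in this model.

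A group of 37 genes had 0 counts in all 4 old replicative libraries and at least 10 counts in every old quiescent library, and 2 genes had the reverse. Independent loss of genes from each library, at each library's own rate within classes of equal abundance, is argued against, since 1000 draws gave at most 21 such genes (median 10, over 10761 genes). A loss specific to these genes in any library with few detected genes remains open: in the 2 young replicative libraries with the fewest detected genes they had 40 zeros of 74 possible, where 1000 draws of as many genes of equal abundance gave at most 29 (median 16), against 2 of 111 in the other young replicative libraries. That split of the young libraries follows detected genes, not a label. Lower expression in replicating cells remains open too and was not separated from it: in young cells 27 of the 37 lay below 0, with a median of -0.61, and edgeR called 0 of them.

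ENSRNOG00000028137 was lower in old than in young quiescent libraries, and so was the sum of the 145 genes over 16-fold higher in replicative cells at both ages (142 ± 21.3 against 266 ± 99.9 CPM; SD, n = 4 and 5; exact permutation test, two-sided, p = 0.0317). Uneven scaling is argued against, since with RLE factors the lowest young quiescent sum was still 1.09 times the highest old one. Residual RNA of replicating cells in the young quiescent libraries cannot be told apart from a difference in the quiescent cells themselves: the levels of these genes in young quiescent and young replicative cells correlated with an r of 0.743 across genes, but choosing genes by their fold ties both levels together. The sums came to 1.03% of the replicative level in old and 1.45% in young islets, and in replicative cells they were 13845 and 18416 CPM (exact p = 0.159).

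The interaction differed from 0 for 4 genes, at -7.368 for ENSRNOG00000024848, -9.029 for ENSRNOG00000062279, -8.677 for ENSRNOG00000051989 and -8.852 for another; the last 3 values belong to genes at 0 in all old replicative libraries and depend on the prior count. Young quiescent replicate 1 had a mean Spearman correlation of 0.9434 with its group, where the next lowest had 0.9611. For ENSRNOG00000024848, old replicative replicate 2 had 0.5221 CPM where the other three had 0, and young quiescent replicate 1 had 18.97 CPM where the next had 8.779. For ENSRNOG00000047374, old quiescent replicate 1 had 1190 CPM where the next had 730.9. For ENSRNOG00000006957, young quiescent replicate 1 had 3.194 CPM where the next had 1.090. For ENSRNOG00000002461, old quiescent replicate 2 had 105.9 CPM where the next had 34.22.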

How the results depend on the processing

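Counts are given in the order replication in old, replication in young, age among quiescent, age among replicative, interaction, with 2053, 368, 4, 1069 and 4 genes in the edgeR 4-group model. DESeq2 gave 3183, 604, 67, 2251 and 296, and limma-voom with quality weights 1055, 2952, 1589, 231 and 2 (both higher, and neither among the 4). The 2-group fits gave 540, 786, 258 and 62, and limma-voom with 1 weight per group, chosen after seeing the data, 639, 704, 507, 29 and 0 (1027 at an unadjusted p under 0.05 for the interaction). With no low-count filter age among quiescent cells gave 8 and the interaction 1. The interaction gave 15 with the filter at 1 CPM, 0 with thinned counts (1156 unadjusted) and 1 with the deposited log2 values. The cause of these changes was not tested, and the 2-group fits changed both the spread estimate and the filter. All other counts under scaling, filters, depth, the 10 most abundant genes and the deposited values lay within 1.5 times the main one.

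Upper-quartile scaling moved the median of all genes from 0.01 to -0.10 for replication in old and from -0.05 to -0.20 for age among replicative cells, and RLE factors moved the former to 0.14. Replication in old gave 937 higher and 1246 lower with upper-quartile scaling, 1209 and 799 with RLE factors and 833 and 222 with quality weights (1068 and 985 in the main model). Replication in young gave 1695 and 1257 with quality weights (336 and 32). With upper-quartile scaling age gave 3 higher and 2 lower among quiescent cells (3 and 1 in the main model) and 373 and 813 among replicative cells (491 and 578). The deposited log2 values gave 806 and 1341 for replication in old, and 1 and 2 and 439 and 1102 for age among quiescent and replicative cells. Age among replicative cells gave 508 and 370 with the filter at 1 CPM and 473 and 385 with thinned counts.

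Leaving out single libraries gave 1134 to 2916 genes for replication in old, 293 to 393 in young, 0 to 13 for age among quiescent, 644 to 2211 among replicative and 0 to 231 for the interaction. For replication in old the count was 1351, 1153 and 1134 without old quiescent replicates 1, 3 and 4. Among replicative cells it was 2211 and 1641 without old replicative replicates 1 and 4, and 695 and 644 without young replicative replicates 2 and 3. Among quiescent cells it was 13, 2 and 2 without old replicates 1, 2 and 4, and 8, 0 and 0 without young replicates 1, 2 and 3. The interaction moved by over 1.5 times in 17 of 18 cases.

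The replicate numbers are not stated to mark a batch. Same-numbered libraries deviated together with a correlation over 0.1 in 7 of 9 pairs (0.0915 and 0.0714 in the others). Of 18 libraries, 17 correlated best with their own number, a hint from the data that the numbers pair them. The main model had no block because no source used here states a batch term, a choice fixed before this check. Its p-values therefore leave out any such pairing. With the number as a fixed replicate block, replication gave 1957 genes in old (700 higher, 1257 lower), 400 in young (317 and 83) and 11 for the interaction (9 higher and 2 lower, against 0 and 4), of which 1 was among the 4; ENSRNOG00000062279 lost its call with nearly the same fitted value (-8.83 against -9.03, adjusted p = 0.114, range 1.82e-06 to 0.648). As a random block in limma-voom it gave 3684 (1002 higher, 2682 lower), 475 (366 and 109), 4, 1730 and 165, and in the 2-group fits, chosen after seeing the data, 473 in old and 1101 in young (681 and 420).

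Of the values of single genes under these alternatives, 338 kept their direction and call, 53 kept their direction and lost the call, and 0 turned. All 12 alternative set tests kept their call. Depth limits genes with few counts, and the main test recovered few 2-fold changes in simulated counts. The gene lists and marker sums fixed in advance were not run, since the files do not pair IDs with names.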

Other observations

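Among the most abundant genes, more were called lower than higher in replicating cells of old islets in the 4-group model. Of the 515 genes with an average log2 CPM of 8 or more, 165 were lower and 14 higher in old replicative cells, 34.8% of the class, and in young cells 14 were lower and 8 higher. The fit of the old libraries alone called 395 genes higher and 145 lower over all abundances, so not all of the 165 calls hold there. The 985 genes lower in old replicative cells took 38.9% of counts in old quiescent libraries and 37.6% ± 4.24 (SD, n = 5) in young quiescent ones. They took 28.1% ± 1.17 (SD, n = 5) in young replicative libraries, between the young quiescent share and the 20.95% of old replicative libraries. The 1068 genes higher in old replicative cells took 1.63% ± 0.147 in young quiescent and 5.82% ± 0.836 in young replicative libraries (SD, n = 5 each). These lists were called for the difference between the old groups, in a model whose filter and spread estimate also use the young libraries.

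Detected genes differed among the young replicative libraries themselves. Thinned to 2723660 counts, replicates 1, 2 and 3 held 21819, 18804 and 19791 genes and replicates 4 and 5 held 14532 and 14031. Old replicative replicates 1 to 4 held 16888, 13899, 11730 and 12435. Among replicative cells 10 genes had 0 counts in all 4 old libraries and at least 10 counts in every young one, and 0 genes the reverse by the same rule.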
